A study of Mus musculus with 6 samples.

How the data were processed

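RNA was measured in long-term haematopoietic stem cells (LT-HSCs) of mice in which IMP1, the RNA-binding protein encoded by Igf2bp1, had been switched on again in adult blood cells. Per the labels' protocols, marrow of donors carrying a conditional IMP1 knock-in at the Rosa26 locus together with the Mx1-Cre transgene, or Mx1-Cre alone, was transplanted into irradiated hosts, and Cre was then induced by poly(I:C), a synthetic double-stranded RNA. Donor-derived cells with the LT-HSC surface phenotype were sorted 8 weeks after the last injection, 200 cells per library, and cDNA was made with the SMARTer Ultra Low RNA kit, which amplifies full-length cDNA from small cell numbers and does not use molecular identifiers. The labels describe 3 biological replicates per genotype.

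The authors deposited raw read counts per Entrez gene for 21761 genes, 1 column per library, per the file headers. TopHat2 2.0.10 and the mm9 mouse build were named in the submitters' processing notes, with no role given. The counting program, its strand setting, the gene annotation and the handling of reads that match several genes were not given in the sources used here. Genes with near-identical copies, or lying over one another, were therefore treated as uncertain. Each column was matched to its library by the name in the header, and 0 columns were left unmatched. Gene symbols were taken from a RefSeq table of the GRCm38.p6 assembly by Entrez identifier, which matched 21615 identifiers. The other 146 identifiers, with 0.0645% of all counts, were kept under their number. Because the reference build differed from mm9, no coordinates are reported, and the reference served for names, transcript length, GC content, gene order and overlaps between genes only.

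Counts were analysed as deposited. The main test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest at the default settings of this version) in R 4.3.3, with trimmed mean of M values (TMM) library scaling, the filterByExpr filter on low counts, genotype as the single term and all 6 libraries in 1 fit. The filter left 12807 genes. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. Levels are TMM-normalised CPM (counts per 1e6 counts of the library), given as mean ± SD over 3 libraries unless stated otherwise. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the whole group and is a lower bound. Where it had 1 to 3 counts, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

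Before the data were examined, 28 gene lists, the alternatives for each result and the rule for naming genes were fixed. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), adjusted over the 26 lists with at least 3 tested members. The list of 13 mitochondrially encoded genes had 0 members in the table, and the sex-linked list had 2 tested members, so neither was tested. The naming rule took the Igf2bp family and the 10 genes with the largest rise and the 10 with the largest fall past the threshold. Where fewer than 10 passed, it filled up with genes of the lowest p. For each list it took members past the threshold over all genes or over the list alone, at most 6, and the 2 most abundant members. Some genes that met the rule are not reported here. Genes named outside that rule are marked as such.

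Other settings fixed beforehand were DESeq2 1.42.0, limma-voom with and without quality weights, edgeR with legacy settings, other library scalings, other low-count filters, other thresholds, the replicate number as a block, other list tests and each library left out in turn. Added after the data were seen were the newer edgeR settings (legacy = FALSE), binomial thinning of all libraries towards 25749898 counts, the smallest total, removal of a smooth trend on transcript length and GC content per library (loess, span 0.4, genes above a mean log2 CPM of 3), and lists without Igf2bp1. For the lists, also after the data were seen, 10000 random lists of other genes matched on length, GC content and abundance as nearly as the other genes allowed were drawn. Length and GC content were those of the longest annotated transcript of each gene and were found for 20328 genes. The transcript present in the cells may be shorter.

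The fit was tested on simulated counts for 12518 genes, with 200 changed by 1 or 3 log2 units. A further small list of genes was shifted down by less than 1 log2 unit. The fit recovered 31% of the genes changed by 1 log2 unit and 92% of those changed by 3 log2 units. Of 130 calls in all, 6 were on genes with no change put in. No libraries were duplicates, since the chi-square per degree of freedom between libraries was at least 61.0 within Control and 142 within IMP1.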

Results

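LT-HSCs, the rare marrow cells that can rebuild blood for life, were profiled by RNA sequencing in 2 genotypes. The IMP1 group carried a Cre-dependent IMP1 knock-in at Rosa26 and the Control group carried Mx1-Cre without it, with 3 libraries each. Control libraries held 27338450, 26326164 and 25749898 counts, and IMP1 libraries held 61916908, 67083116 and 50220629, on average 2.26 times as many. Between 13282 and 14056 genes had a count in the Control libraries and between 14388 and 14563 in the IMP1 libraries. The 10 most abundant genes took 6.06% to 6.87% of the counts of a library. Depth therefore differed with genotype, and no label gave a batch by which it could be separated.

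The comparison asked what re-expressing IMP1, an RNA-binding protein of fetal tissues, changed in adult LT-HSCs. Igf2bp1 (Entrez gene 140486), which encodes IMP1, had 0, 0 and 1 counts in the Control libraries and 1870, 2084 and 2016 in the IMP1 libraries. Its level was 0.0133 ± 0.0231 CPM in Control and 32.8 ± 5.28 CPM in IMP1 cells (SD, n = 3), a ratio of 2482 with a counting interval of 445 to 98048. The fitted log2 fold change was 11.01 (SE 0.73, adjusted p = 0.00399). The species of the knock-in cDNA was not given in the sources used here, and reads of a non-mouse cDNA would be undercounted at this gene. The paralogues showed no detectable difference. Igf2bp2 stood at 7.30 ± 2.69 against 6.11 ± 2.15 CPM (log2 fold change −0.26, adjusted p = 0.881) and Igf2bp3 at 2.51 ± 0.583 against 2.56 ± 1.77 CPM (0.03, adjusted p = 0.992). The family list did not pass (camera adjusted p = 0.135, and 0.486 with an estimated correlation, while fry gave 0.00188), with 1 of its 3 members called higher and 1 higher adjusted over the list alone. Gt(ROSA)26Sor, the noncoding transcript of the locus that received the knock-in, was chosen from the design before its values were seen and lay outside the naming rule. It stood at 112 ± 12.7 CPM in Control and 56.8 ± 12.5 CPM in IMP1 cells (log2 fold change −0.98, SE 0.21, adjusted p = 0.0979), which did not pass the threshold. DESeq2 gave it an adjusted p of 0.000976, the lowest over 18 alternatives, of which the highest was 0.261. Its span overlaps Thumpd3, so without strand information reads of both cannot be told apart. Leaving out Control 3, the library with the single Igf2bp1 count, raised the adjusted p of Igf2bp1 to 0.0812, and limma-voom gave 0.0801. Over 17 alternatives its adjusted p ranged from 1.07e-15 to 0.0812.

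Beyond Igf2bp1, rises were found for the cytokine subunit gene Ebi3, the secreted protein gene Serpinf1 and the PI3-kinase regulatory subunit gene Pik3r1. The transcripts that fell included the myeloid and lymphoid genes Plac8, Nkg7 and Lat2, the GDP dissociation inhibitor gene Arhgdib, and the ribosomal protein genes Rpl8 and Rpsa. In all, 27 of 12807 genes passed the edgeR threshold, 9 higher and 18 lower in IMP1 cells. Without TMM scaling 9 were higher and 7 lower, and with the length and GC trend removed 7 were higher and 6 lower. At an unadjusted p under 0.05 there were 854 higher and 977 lower genes. The values of the groups did not overlap for 2800 genes, or 21.9%, where chance gives 10%. The first principal component held 28.9% of the variance and separated the groups, from −78.9 to −36.8 in Control and from 38.04 to 70.02 in IMP1 libraries. Across genes, which are not independent replicates, Pearson's r was 0.883 to 0.898 between Control libraries, 0.878 to 0.896 between IMP1 libraries and 0.857 to 0.885 between groups. Most calls rested on all 6 libraries, since 2 genes passed without Control 1, 2 without Control 2, 0 without Control 3, 2 without IMP1 1, 1 without IMP1 2 and 2 without IMP1 3. In those 6 fits Igf2bp1 was called in 5, Arhgdib and Plac8 in 1 each and the rest of the 27 genes in 0, while all 27 kept their direction, and at an unadjusted p under 0.05 the fit without Control 3 held 1627 genes.

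**Figure D1:**
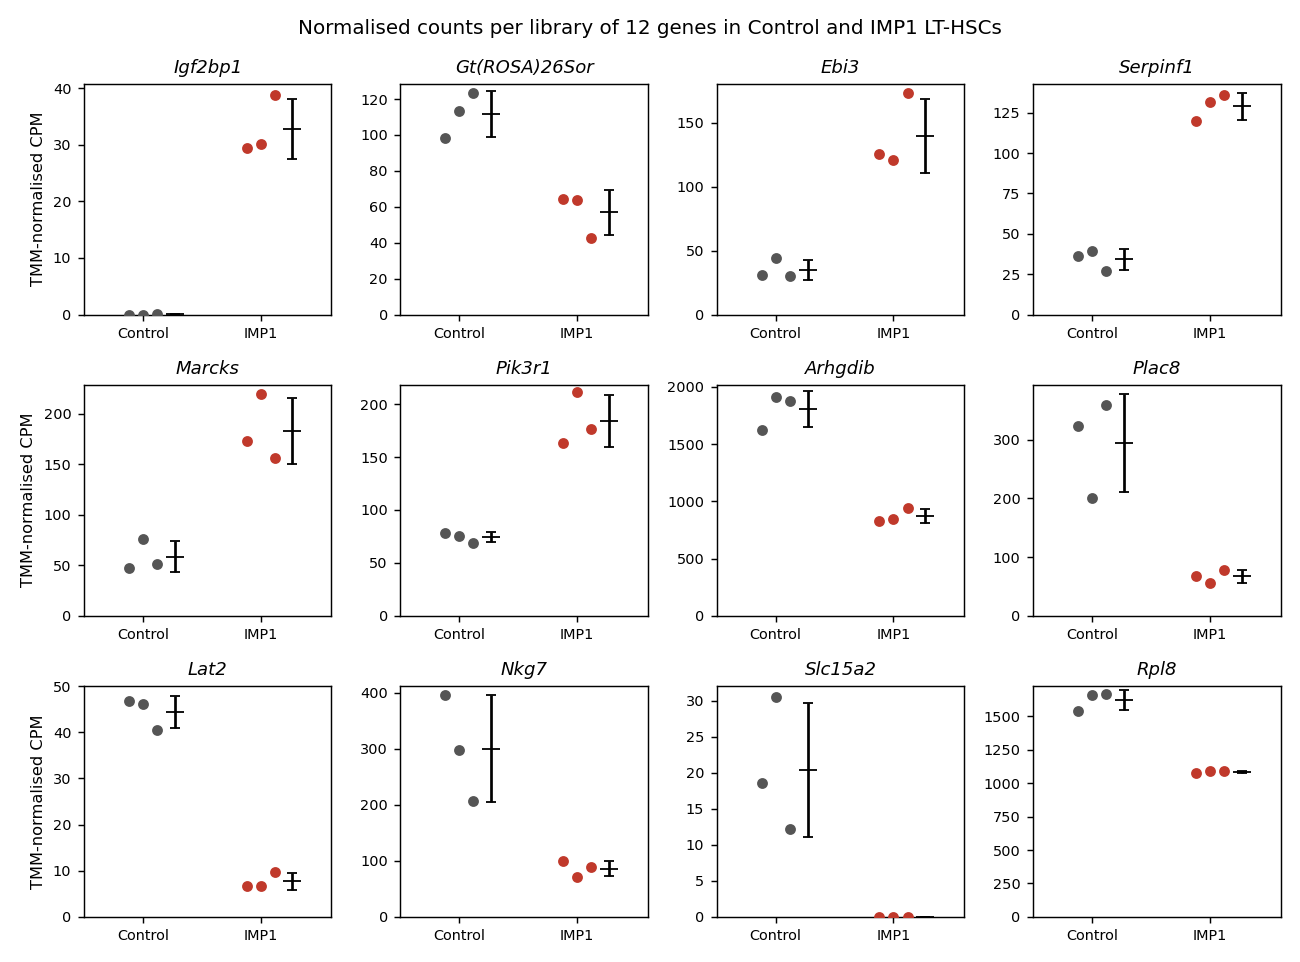
Normalised counts per library in CPM (vertical axes, from 0) of 12 genes in 3 Control (grey) and 3 IMP1 (red) libraries, each point 1 library, with the mean and SD drawn beside each group. The IMP1 points of Igf2bp1, Ebi3, Serpinf1, Marcks and Pik3r1 lie above all Control points, and those of the other 7 genes, among them Slc15a2 at 0 CPM and Gt(ROSA)26Sor, which did not pass the threshold, lie below them.

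Among the genes called higher, Ebi3, the shared subunit of interleukins 27 and 35, rose from 35.0 ± 7.75 to 140 ± 29.0 CPM (log2 fold change 2.00, SE 0.23, adjusted p = 0.0287). Serpinf1, which encodes pigment epithelium-derived factor, rose from 34.1 ± 6.33 to 129 ± 8.45 CPM (1.92, SE 0.19, adjusted p = 0.0287). Marcks, an actin-binding substrate of protein kinase C, rose from 58.5 ± 15.5 to 183 ± 33.1 CPM, and Lst1 from 20.3 ± 1.12 to 61.3 ± 1.16 CPM. Pik3r1 rose from 74.4 ± 4.97 to 184 ± 24.6 CPM (1.30, SE 0.15, adjusted p = 0.0287). The beta-globin gene Hbb-b1 went from 16.9 ± 2.99 to 62.6 ± 12.6 CPM (1.89, SE 0.26, adjusted p = 0.0448). It has near-identical copies among which reads may be split, and IMP1 1 also held the red-cell transcripts Car1 and Rhd, named outside the rule, which were at most 0.0380 and 0 CPM in the Control libraries before TMM scaling. Arhgap28, with the lowest p among genes with a positive change that were not called, stood at 0.497 ± 0.272 and 14.9 ± 6.68 CPM (4.90, adjusted p = 0.0516).

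Among the 18 genes called lower, Slc15a2, a peptide transporter gene, had 1571 counts over the Control libraries (20.4 ± 9.30 CPM) and 0 over the IMP1 libraries, at least 1260-fold lower. Tespa1, a gene of T cell receptor signalling, had 592 and 0 counts, at least 475-fold lower (adjusted p = 0.0473). It passed in 5 of 17 alternatives. The adaptor gene Lat2 fell from 44.4 ± 3.50 to 7.72 ± 1.81 CPM (log2 fold change −2.53, SE 0.29, adjusted p = 0.0287). Plac8 fell from 294 ± 83.3 to 67.6 ± 11.05 CPM (−2.12, SE 0.24, adjusted p = 0.0287) and Nkg7, a cytotoxic granule gene, from 300.4 ± 94.96 to 86.3 ± 13.6 CPM (−1.80, SE 0.24, adjusted p = 0.0448). Serpinb1a, an inhibitor of neutrophil proteases, fell from 372 ± 89.9 to 138 ± 24.4 CPM, and Litaf from 152 ± 18.9 to 63.8 ± 4.64 CPM. Tmem254a, which has near-identical copies and is therefore uncertain, went from 245 ± 24.9 to 103 ± 7.60 CPM. Arhgdib fell from 1804 ± 157 to 870 ± 60.3 CPM (−1.05, SE 0.09, adjusted p = 0.0183). Changes of 0.58 to 0.97 on the log2 scale were found for other genes called lower, among them the ribosomal protein genes Rpl8 and Rpsa, the mitochondrial genes Slc25a5, which encodes an adenine nucleotide carrier, and Etfb, which encodes an electron transfer flavoprotein subunit, and Gm2a, Arf1 and Mcrip1. With the length and GC trend removed, 13 of the 27 calls were kept. Those of Tespa1 (adjusted p = 0.0776) and Nkg7 (adjusted p = 0.0970) were among the calls lost. Among the lost calls, Rpl8 shrank from −0.58 to −0.36 and Rpsa from −0.58 to −0.41, while others kept most of their fold, as Hbb-b1 at 1.89 (SE 0.26) in both fits, Marcks at 1.65 and 1.58, Litaf at −1.25 and −1.18 and Serpinb1a at −1.43 and −1.35. Loss of a call therefore did not show that the trend accounted for it. Slc15a2 overlaps Gm8425, Rpsa overlaps Gm5922, Etfb overlaps Cldnd2 and Ebi3 overlaps Zfp119b in the reference, and ribosomal protein genes have many pseudogenes, so their counts depend on how shared reads were assigned.

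Messenger RNAs for energy metabolism and for the ribosome were lower as groups in the IMP1 libraries by the main list test. Other settings, given below, weakened this, most of all for the ribosome. Of 77 nuclear genes of oxidative phosphorylation, 67 had negative log2 fold changes, with a median of −0.22 (camera adjusted p = 6.46e-08, and adjusted p = 0.306 with an estimated correlation). None passed over all genes (0 of 77), and 5 were lower adjusted over the list alone. These were Sdha, a subunit of succinate dehydrogenase, at 446 ± 40.9 against 276 ± 32.5 CPM, and Uqcr11, Ndufs7, Atp5j2 and Ndufs8. The abundant ATP synthase genes Atp5b (842 against 753 CPM) and Atp5a1 (809 against 767 CPM) did not pass. Of 79 cytosolic ribosomal protein genes, 71 were negative, with a median of −0.20 (adjusted p = 1.56e-07, and adjusted p = 0.634 with an estimated correlation). The estimated correlation was 0.613, far above the preset 0.01, so the p from the preset value is too low for this list. Rpl8 (1622 ± 74.1 to 1086 ± 7.66 CPM) and Rpsa (3968 ± 219 to 2662 ± 238 CPM) were among the 3 called over all genes, and 28 were lower adjusted over the list alone, among them Rps2, Rps18, Rpl3 and the abundant Rps6 (5525 ± 230 to 4584 ± 301 CPM). Of 24 glycolysis genes, 19 were negative, with a median of −0.35 (adjusted p = 0.00277, and adjusted p = 0.187 with an estimated correlation). None passed over all genes (0 of 24), and 9 were lower adjusted over the list alone. Ldha, which makes lactate, stood at 1249 ± 39.1 against 711 ± 149 CPM, Pkm at 1064 ± 161 against 645 ± 39.3, Gapdh at 1185 ± 67.1 against 745 ± 105, and Aldoa at 1125 ± 148 against 750 ± 46.5, with Eno1 and Pgk1 besides. Ribosome biogenesis and translation factors did not move as a group (37 members, 18 positive, median −0.01, adjusted p = 0.517), with 0 members past either threshold, and the abundant members Eef1a1 (14432 against 12745 CPM) and Npm1 (2842 against 2918 CPM) did not pass. With the length and GC trend removed, the medians of the ribosomal protein and oxidative phosphorylation lists shrank to −0.03 (adjusted p = 0.0851) and −0.08 (adjusted p = 0.0102), and that of glycolysis to −0.24 (adjusted p = 0.0102), while that of the actin list became −0.16 (adjusted p = 0.0202). The directional fry test, run with the trend still in the values, did not pass for ribosomal proteins either (adjusted p = 0.0825). It passed for oxidative phosphorylation (adjusted p = 0.0146), glycolysis (0.00230) and actin genes (0.00951). Of the lists described below, it passed for imprinted genes (0.00928), the let-7 list with Igf2bp1 in it (0.00296) and mast cell markers (1.19e-05).

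**Figure D2:**
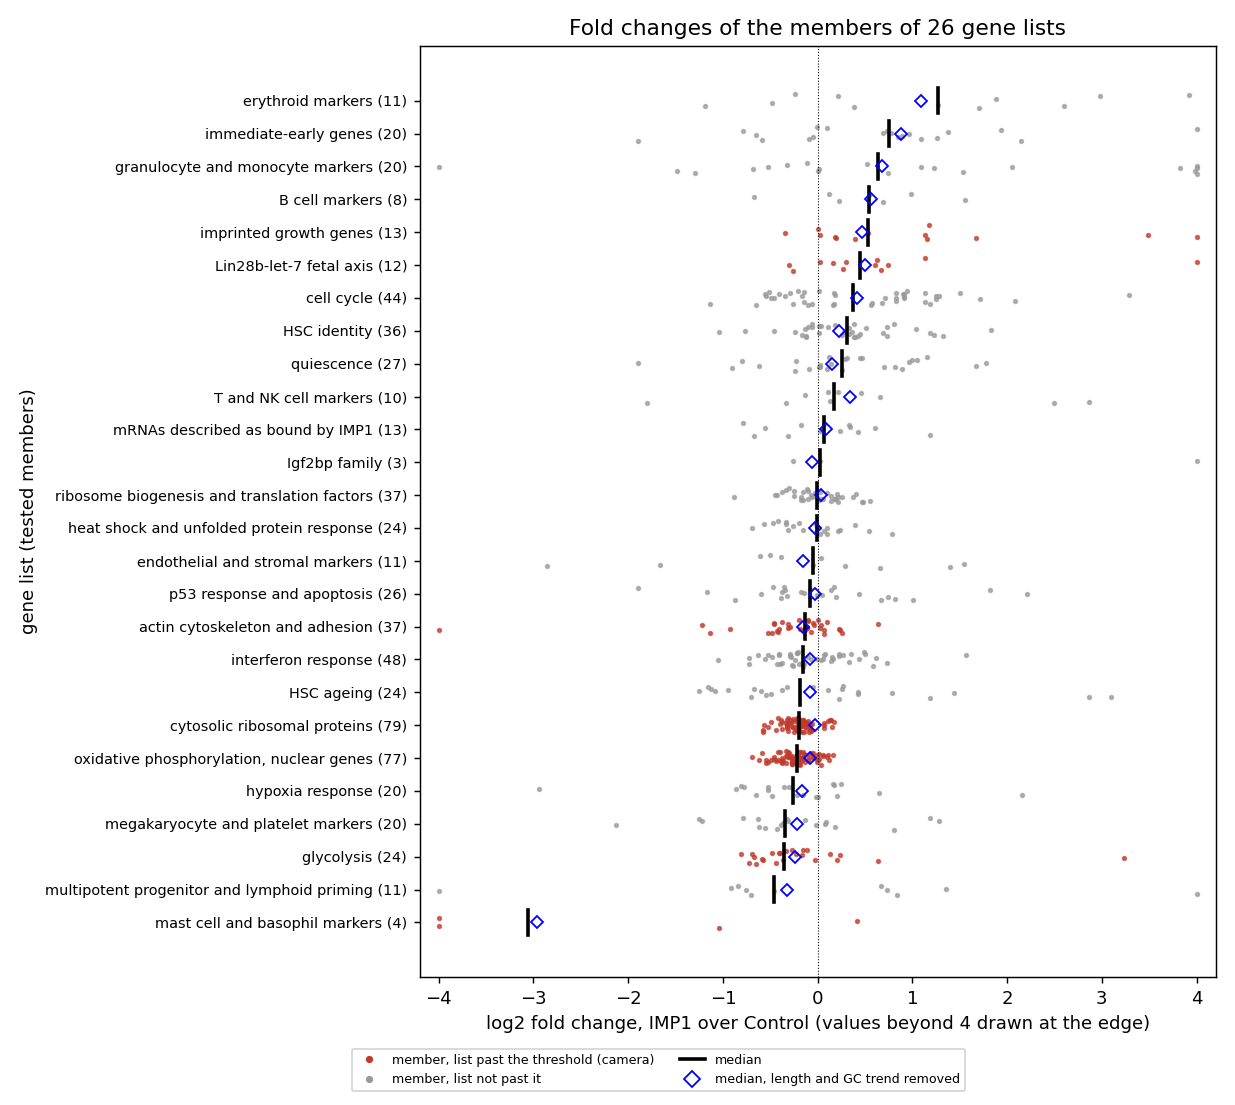
Log2 fold changes, IMP1 over Control (horizontal axis, values beyond 4 drawn at the edge), of the tested members of 26 gene lists (vertical axis), each point 1 gene, red where the list passed the camera threshold. Black bars are list medians and blue diamonds medians after the trend on transcript length and GC content was removed, which for ribosomal proteins moved from −0.20 to −0.03.

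Fold changes followed transcript length. Among genes above a mean log2 CPM of 3, the median log2 fold change went from −0.17 in the bin of the shortest transcripts to 0.17 in that of the longest, of 4 bins of equal size, and Spearman's correlation across genes was 0.301 with length and −0.190 with GC content. Slopes on log2 length were fitted to log2 CPM after each gene's mean over all libraries was subtracted. They lay between −0.0927 and −0.0581 in the 3 Control libraries and between 0.0677 and 0.0778 in the 3 IMP1 libraries. Such slopes are relative, so their opposite signs show only that the groups differed in their length trend. By the longest annotated transcript of each gene, the members of the ribosomal protein list had a median length of 1059 bases and those of the oxidative phosphorylation list 1141 bases.

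**Figure D3:**
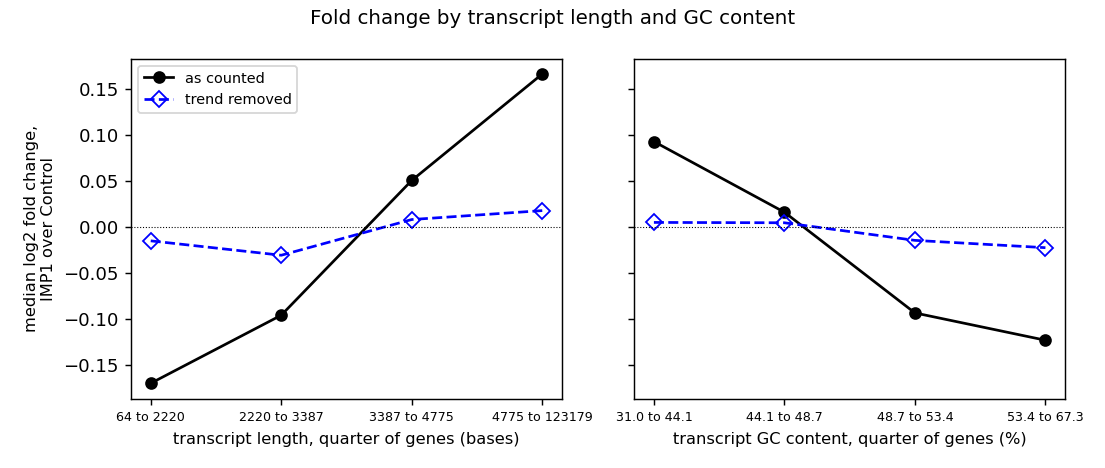
Median log2 fold change, IMP1 over Control (vertical axis), of genes in 4 bins of transcript length in bases (left) and of GC content in percent (right). Filled circles, as counted, run from −0.17 to 0.17 with length and from 0.09 to −0.12 with GC content, and open diamonds show the medians after the trend was removed.

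Imprinted growth genes, which are expressed from 1 parental allele and include regulators of fetal growth, were higher as a group. Of 13 tested members, 12 were positive, with a median log2 fold change of 0.53 (adjusted p = 0.00186, and adjusted p = 0.187 with an estimated correlation). None passed over all genes (0 of 13), and 3 were higher adjusted over the list alone. Cdkn1c, which encodes the cell cycle inhibitor p57, stood at 6.74 ± 1.34 against 21.5 ± 4.02 CPM (1.68), and the noncoding transcripts Meg3 and Rian of one imprinted cluster at 1.48 ± 1.10 against 16.7 ± 5.16 CPM (3.49) and 0.266 ± 0.306 against 9.41 ± 4.08 CPM (5.12). The abundant members Impact (429 against 487 CPM) and Gnas (204 against 207 CPM) did not pass. The list of the Lin28b and let-7 axis, a circuit of fetal haematopoiesis in which Igf2bp1 itself is a member, passed (12 members, 10 positive, median 0.45, adjusted p = 0.0124, and adjusted p = 0.190 with an estimated correlation). Igf2bp1 was its single member past the threshold over all genes and adjusted over the list alone (1 of 12). Hmga1 stood at 92.1 ± 22.2 against 142 ± 38.4 CPM and Mycn at 265 ± 58.0 against 327 ± 64.3 CPM, neither past it. Without Igf2bp1 the list had an adjusted p of 0.0918, without the library IMP1 1 one of 0.0723, and with the strict filter, which removes Igf2bp1, one of 0.156. Lin28b itself, named outside the rule, was not tested, with 0 counts in each Control library and 0, 5 and 51 in the IMP1 libraries. With the length and GC trend removed, the imprinted list and the let-7 list with Igf2bp1 in it still passed (medians 0.47 and 0.50, adjusted p = 0.00440 and 0.0137). Of 21 RNAs described as bound by IMP1, 13 were tested, and they did not pass as a group (8 positive, median 0.07, camera adjusted p = 0.842). That test asks for a shared direction only. Among the untested members, named outside the rule, Igf2 had at most 3 counts in any library. H19 had 0 counts in each Control library and 0, 201 and 75 in the IMP1 libraries. Myc, a described target, stood at 382 ± 16.0 against 222 ± 43.1 CPM (−0.79, adjusted p = 0.0760 over all genes) and was the 1 member lower adjusted over the list alone, while Actb stood at 7850 ± 930 against 8218 ± 724 CPM (0.07, adjusted p = 0.818).

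Genes of LT-HSC identity did not pass as a group (36 members, 25 positive, median 0.31, adjusted p = 0.0772, with 0.0491 without Control 3, 0.182 without Control 1, 0.0203 on voom values and 0.306 with an estimated correlation). Mllt3, a regulator of HSC self-renewal, was 1 of 2 members higher adjusted over the list alone, at 247 ± 49.0 against 398 ± 39.6 CPM. The abundant Meis1 (999 against 846 CPM) and Fli1 (632 against 719 CPM) did not pass. The quiescence list did not pass (27 members, median 0.26, adjusted p = 0.266). Adjusted over the list alone, 3 members were higher, namely Cdkn1c, Bmi1 (30.0 ± 10.6 against 62.2 ± 5.94 CPM) and Rbl2, and 3 were lower, namely Btg2 (28.1 ± 8.94 against 7.54 ± 3.19 CPM) and the cell cycle inhibitors Cdkn1b (103 ± 24.7 against 59.1 ± 10.6 CPM) and Cdkn2c. The abundant Txnip (587 against 810 CPM) and Btg1 (196 against 235 CPM) did not pass. The cell cycle list did not pass (44 members, 27 positive, median 0.38, adjusted p = 0.0772), though it did without Control 1 (0.0118) and without IMP1 2 (0.000216), against 0.644 without IMP1 1 and 0.715 with an estimated correlation. The mitotic genes Ube2c (10.4 ± 3.72 against 44.1 ± 15.6 CPM) and Cenpa (23.2 ± 3.33 against 51.1 ± 10.6 CPM) were its 2 members higher adjusted over the list alone, and Stmn1 (1423 against 1119 CPM) and Hmgb2 (413 against 469 CPM) did not pass. Immediate-early genes did not pass (20 members, median 0.75, adjusted p = 0.186, with 0.0294 without IMP1 3 and 0.750 without IMP1 2), with 1 higher, Fos, and 2 lower, Btg2 and Myc, adjusted over the list alone. Fos was at 0.443 CPM in IMP1 3 and 66.4 CPM in IMP1 2, and Nfkbia (158 against 157 CPM) did not pass. Genes described as rising in aged HSCs did not pass (24 members, adjusted p = 0.465), and their median of −0.19 and mean of 0.07 differed in sign. Dsg2 was higher and Aldh1a1 (240 ± 65.3 against 107.8 ± 10.999 CPM) and Selp (55.1 ± 18.4 against 23.2 ± 4.63 CPM) were lower adjusted over the list alone, and Nupr1 (395 against 261 CPM) did not pass.

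Actin cytoskeleton and adhesion genes were lower as a group (37 members, 27 negative, median −0.13, adjusted p = 0.00857, and adjusted p = 0.187 with an estimated correlation). None passed over all genes (0 of 37), and 3 were lower adjusted over the list alone, Actg1 (2619 ± 131 to 1821 ± 215 CPM), the small GTPase gene Cdc42 (1158 ± 73.7 to 843 ± 82.3 CPM) and the actin nucleation gene Arpc1b, while Actb was not among them. Stress and signalling lists did not pass. The hypoxia list (20 members, median −0.26, adjusted p = 0.0947, with 0.0359 without Control 1, 0.258 without Control 2 and 0.0386 on voom values) had 5 members lower adjusted over the list alone, Ndrg1 (145 ± 41.1 against 18.8 ± 11.7 CPM), Ldha, Pgk1, Bnip3l and Higd1a. The interferon list (48 members, 29 negative, median −0.15, adjusted p = 0.0955, with 0.0174 without IMP1 2 and 0.605 without IMP1 1) had 0 members past either threshold, with Psmb8 at 579 ± 34.7 against 430 ± 65.8 CPM and Gbp7 at 429 ± 37.1 against 350 ± 55.8 CPM. The p53 and apoptosis list (26 members, adjusted p = 0.549) had a median of −0.08 and a mean of 0.04. Adjusted over the list alone, its member Zmat3 was higher (4.15 ± 0.428 against 14.7 ± 2.55 CPM) and its members Btg2 and Trp53 (519 ± 37.8 against 398 ± 26.2 CPM) were lower, and Casp8 (174 against 164 CPM) did not pass. The heat shock and unfolded protein list (24 members, median −0.01, adjusted p = 0.266, with 0.0391 without IMP1 1 and 0.833 without IMP1 3) had 0 members past either threshold, and its most abundant members Hspa8 and Hsp90ab1 stood at 7135 ± 898 against 5667 ± 1064 CPM and at 2726 against 2379 CPM.

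Markers of other blood lineages, which the sort was meant to exclude, were mostly low and uneven. Of the 4 tested mast cell and basophil markers, 3 were negative, and the list passed (median −3.05, also with Cyp11a1 at its bound, adjusted p = 0.00514, and adjusted p = 0.187 with an estimated correlation). None passed over all genes (0 of 4) and 2 were lower adjusted over the list alone. Fcer1a, the receptor for immunoglobulin E, had 924, 614 and 533 counts in Control and 151, 0 and 0 in IMP1 libraries. Cyp11a1 had 287 counts over the Control and 0 over the IMP1 libraries, at least 230-fold lower, and Cpa3 (12.001 ± 3.73 against 5.84 ± 7.74 CPM) did not pass. Progenitor and lymphoid priming genes did not pass (11 members, median −0.46, mean 0.10, adjusted p = 0.517). Cd27 (267 ± 32.4 against 141 ± 24.7 CPM) and Cd34 (283 ± 29.2 against 168 ± 38.8 CPM), the latter a marker the cells were sorted against, were its 2 members lower adjusted over the list alone. Megakaryocyte and platelet markers did not pass (20 members, median −0.35, adjusted p = 0.0947, with 0.00670 without Control 2, 0.231 without Control 1 and 0.0416 without the low-count filter). Adjusted over the list alone, 2 members were higher and 6 were lower, among them Cd9 (516 ± 67.0 against 299.96 ± 24.96 CPM), F2rl2, Plek, Nfe2 and Selp. Erythroid markers did not pass (11 members, 8 positive, median 1.27, adjusted p = 0.0571, with 0.0361 without Control 2 and 0.00229 without IMP1 2). They did with the length and GC trend removed (median 1.09, adjusted p = 0.0202) and without the low-count filter (0.0457). The group depended on IMP1 1, without which the adjusted p was 0.412, and it was 0.607 with an estimated correlation. Hbb-b1 was called, and Hbb-bs (10.4 ± 2.37 against 33.8 ± 9.58 CPM), Ermap (18.6 CPM in IMP1 1) and Tfrc were also higher adjusted over the list alone, 4 in all, while the abundant Car2 (3853 against 4463 CPM) and Blvrb (75.8 against 64.4 CPM) did not pass. Granulocyte and monocyte markers did not pass (20 members, median 0.63, adjusted p = 0.549, with 0.0356 without IMP1 3 and 0.861 without IMP1 2). Lcn2, S100a9 and S100a8 were higher and Lyz2 (463 ± 45.9 against 288 ± 23.0 CPM) and Mpo were lower adjusted over the list alone. S100a8 stood at 8.91 ± 3.43 against 142 ± 118 CPM, with 11.4 CPM in IMP1 3 and 243 CPM in IMP1 1, and Prtn3 (258 against 206 CPM) did not pass. B cell markers did not pass (8 members, 7 positive, median 0.54, adjusted p = 0.0560, with 0.00161 without Control 3, 0.0299 without IMP1 1, 0.156 without Control 1 and 0.607 with an estimated correlation). They did with the length and GC trend removed (median 0.56, adjusted p = 0.0137), with the strict filter (0.0221), without a filter (0.0233) and on voom values (0.0158). The list had 0 members past either threshold. Its most abundant members were Cd74 (589 ± 291 against 1163 ± 129 CPM) and H2-Aa (274 against 399 CPM). T and NK cell markers did not pass (10 members, median 0.17, adjusted p = 0.705), although Nkg7 was called lower and was the 1 member past the threshold over the list alone, while Lat (63.3 against 57.7 CPM) was not. Endothelial and stromal markers did not pass (11 members, median −0.05, adjusted p = 0.576), with Bgn (94.1 ± 42.8 against 13.0 ± 7.91 CPM) lower adjusted over the list alone and Emcn (53.9 against 65.8 CPM) not past it. Of the sex-linked genes, Xist, which silences 1 X chromosome in female cells, stood at 189 ± 33.7 against 370 ± 44.1 CPM (0.97, adjusted p = 0.0614), and Tsix, which overlaps it on the other strand, at 4.16 ± 1.24 against 3.03 ± 1.89 CPM. Genes of the Y chromosome had between 0 and 6 counts in each library.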

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

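The fits with legacy = FALSE, equal library totals or the length and GC trend removed, and the lists without Igf2bp1, were chosen after the data were seen. All alternatives below are set against 9 higher and 18 lower genes. DESeq2 called 304 higher and 390 lower, limma-voom 1 and 10, the strict filter 16 and 37, and an adjusted p under 0.1 gave 93 and 138. Lower genes numbered 7 with library totals only, 36 with legacy = FALSE, 6 with the length and GC trend removed and 10 at a fold of at least 2. Leaving out 1 library gave 0 to 2 higher and 0 to 1 lower genes, in part from fewer samples. The cause of the other shifts was not tested. The planned legacy = TRUE equals the default of this edgeR version and moved nothing. The Igf2bp1 log2 fold change was 10.16 with limma-voom, no longer past the threshold, and between 10.50 (without Control replicate 1) and 13.60 (without Control replicate 3) with 1 library left out. The strict filter removed the gene. Of the lists, 7 passed, 0 did with an estimated correlation, and 8 to 10 did with 1 library left out. The estimated correlation was 0.613 for ribosomal proteins and 0.127 for oxidative phosphorylation, above the preset 0.01. It lay below 0.01 for the imprinted (−0.0581), let-7 (−0.0648), glycolysis (−0.0194), actin (−0.0180) and mast cell (−0.283) lists. The higher p of those lists with an estimated correlation therefore does not show that their members vary together. Replicate numbers did not pair the libraries, since deviations correlated at −0.00831 to 0.0310 for equal numbers and −0.0302 to 0.0176 for others. The replicate block left 1 higher and 3 lower genes and 11 lists. Among values of single named genes, 1939 kept direction and side of the threshold, 87 moved past it and 225 no longer passed. Among those of single lists the numbers were 426, 27 and 12. None reversed as a called value. All 27 genes tested kept their direction in every alternative that tested them. In simulated data 31% of changes of 1 log2 unit were recovered, so smaller ones were mostly out of reach.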

Other observations

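The tests on thinned call counts, on cell cycle phases and on transcripts private to a library were chosen after the data were seen. The cell cycle list was divided by function after its values were seen, so the counts depend on that choice. Of its 44 tested members, Cks1b (−0.14), Cks2 (−0.05), Stmn1 (−0.35) and Hmgb2 (0.19) were placed in neither part, although Cks1b and Cks2 are often counted with G2 and mitosis. The 22 genes placed there, among them Mki67, Top2a, Aurka and Nusap1, had positive log2 fold changes, with a median of 0.91, and 0.96 with the length and GC trend removed. Of 18 genes of G1/S and DNA replication, 14 were negative, with a median of −0.28, and −0.24 with the trend removed. Mean log2 CPM of the mitotic genes was 4.48, 3.93 and 4.40 in Control and 5.72, 4.59 and 5.51 in IMP1 libraries, a difference of 1.00 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). For the replication genes it was 6.587, 6.002 and 5.997 against 6.52, 5.46 and 6.06 (difference −0.18, exact permutation p = 0.6). The named genes were chosen after their values were seen. Mki67 stood at 48.1 against 110 CPM and Nusap1 at 21.6 against 70.9 CPM, while the replication licensing genes Mcm3 (269 against 171 CPM) and Mcm7 (291 against 204 CPM) stood lower. None of these 4 passed over all genes.

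Transcripts of more mature lineages appeared unevenly over libraries, given here in CPM before TMM scaling. IMP1 2 held Igll1 (34.3), Cd79a (17.4), Ebf1 (14.7) and Vpreb3 (10.5), early B-lineage genes that were at most 0.976 in each other library. IMP1 1 held Car1 (151) and Rhd (25.1) of red cell precursors, with Car1 also at 15.0 in IMP1 3. Neutrophil transcripts were highest in IMP1 1, with S100a8 at 250, S100a9 at 194, Ngp at 177 and Ltf at 47.5. In IMP1 2, S100a8 stood at 176 and S100a9 at 109, against at most 11.5 and 4.29 in Control libraries, and Retnlg reached 60.5 in IMP1 2 and 0 elsewhere. Conversely Mpo was at 24.6, 7.10 and 0.350 in Control and 0.0320, 0 and 0 in IMP1 libraries. Genes were taken as private to a library with at least 50 counts there and at least 90% of the CPM summed over libraries. Of 5 B cell markers private to any library, 4 were private to IMP1 2, which held 30.3% of all 380 private genes (one-sided Fisher's exact test, lowest adjusted p = 1 over 42 tests of lists and libraries). So few markers could not have passed, and independent loss or gain of single transcripts stays open. A few carried-over cells, RNA of other cells, or primed LT-HSCs may each account for the transcripts and also stay open, since sorted pools give no value per cell and the deeper IMP1 libraries held more private genes (112, 115 and 78, against 29, 24 and 22 in Control).

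The lower ribosomal protein and oxidative phosphorylation mRNAs may reflect the trend of fold change with transcript length. The ribosomal protein median of −0.20 lay at percentile 74.1 of 10000 lists of other genes matched on length, GC content and abundance (median −0.20, 95% range −0.27 to −0.16). The match was incomplete, as the mean log2 CPM was 10.28 in the list and 9.25 in its matched lists and the median length 1059 and 1216 bases. For oxidative phosphorylation the median of −0.22 lay at percentile 31.4 (median −0.20, range −0.26 to −0.14). Short transcripts outside these lists thus differed about as much. Medians stayed at −0.20 and −0.22 after thinning all libraries to equal totals. Thinning keeps each gene's expected share of its library, so it could hardly have moved the medians of these abundant genes. It also does not address any difference in preparation that went with depth. Whether the trend itself comes from cDNA synthesis or from the genotype stays open. The relative slope was lower in each Control library than in each IMP1 library, so it followed genotype. The actin list (percentile 38.4) and that of the Lin28b and let-7 axis (97.0) lay within the 95% range of their matched lists. Yet both kept their size with the trend removed (medians −0.13 and −0.16, 0.45 and 0.50, adjusted p = 0.0202 and 0.0137). The let-7 list still held Igf2bp1 there, and without Igf2bp1 it did not pass as counted (camera adjusted p = 0.0918). With the trend removed, it was not tested without Igf2bp1. The lists of glycolysis (percentile 0.690), imprinted genes (98.9) and mast cell markers (0) lay further out among their matched lists. So did lists that did not pass, upward for HSC identity, cell cycle and immediate-early genes (each 100) and for granulocyte, erythroid and B cell markers (each 99.97 or more), and downward for progenitor and lymphoid priming (0.210), megakaryocyte markers (0.540) and hypoxia (1.65). Matched genes were drawn independently, so these ranges leave out correlation among members and are too narrow for lists that vary together. Among the lists that did not pass but lay further out, the estimated correlation ran from 0.00571 for HSC identity to 0.514 for cell cycle. Such percentiles therefore do not show that a list moved.

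The count of 27 genes was also weighed against depth, chance and DNA carried along with the knock-in. At equal totals 31 genes passed, among them all 27, so these calls did not need the extra counts of the IMP1 libraries. Thinning keeps each gene's expected share of its library, so it cannot address differences in preparation that went with depth. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split that reached 27 genes (highest other 0, with 352 to 478 genes at an unadjusted p under 0.05 in edgeR) and the 1 split that reached 7 lists (highest other 4). Donor-strain DNA kept around Rosa26 would be expected to alter neighbouring genes. Of the 27 calls, 0 lay among the 100 tested neighbours on each side. So few calls would seldom fall among 200 genes in any case, so this count decides little. An unadjusted p under 0.05 was found for 13% of those 200 against 14.3% of other genes (Fisher's exact p = 0.684). These neighbours thus showed no detectable excess of change, and donor-strain DNA further away was not tested. The genotype itself, the transplanted donors and any library batch that followed genotype may each contribute and could not be separated by this design.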
